A study of Mus musculus with 6 samples.

How the data were processed

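Total RNA from 6 samples of mouse bone marrow MSCs (3 with control lentivirus, 3 with miR-30e lentivirus) was hybridised to Affymetrix arrays. Per the labels' protocols, RNA was extracted with a commercial kit, its integrity was read on an Agilent Bioanalyzer, and cDNA primed with an oligo(dT) T7 primer was transcribed into biotin-labelled cRNA. Groups and replicate numbers were taken from the sample titles. Other experiments of the study, in smooth muscle cells and with an antisense oligonucleotide, were not analysed here.

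The deposited value table held 28815 probe sets by 6 arrays, with signed values from -3.75 to 4.51 taken as log2 values from their range. The log base, background correction, summarization and normalization that the authors used are not given in the sources used here. Each probe set was centred on its median over the 6 arrays (largest absolute median 7.02e-07), so levels, signal over background and the spread of technical controls were lost, and no dim gene could be told from a bright one. The medians of the arrays lay between -0.018 and 0.0068, within the 0.1 set beforehand, and the table was used without further normalization. The direction of every difference was miR-30e minus control. No genome build was named and no coordinate was used.

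Gene names came from the platform annotation, updated through gene identifiers to the mouse RefSeq gene table of assembly GRCm38.p6 (21689 of the 21780 probe sets with 1 symbol matched). Several symbols were attached to 1605 probe sets and none is named here for 5430, and these 7035 were set aside (0 of them passed with limma when tested, and 361 had an unadjusted p under 0.05). Probe sets of one gene were averaged, which left 19935 genes. Of the 998 genes with more than 1 probe set, 253 had probe sets whose differences disagreed in sign, among them 1 of the 9 such genes that the gene rule named. Runx2 and some other list members had no probe set carrying that symbol alone and were not analysed here.

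Genes were tested with lmFit and eBayes in limma 3.58.1 (R 4.3.3), with the group as the sole term and Benjamini-Hochberg adjustment over all genes, at an adjusted p under 0.05. The 29 gene lists, covering the fates of marrow stromal cells, published miR-30 targets, signalling, matrix, metabolism and markers of other cells, were written before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were tested with camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, which called 16 (5 higher, 11 lower). With an estimated correlation 0 were called. The fry test for movement in 1 direction called 0, and fry for change in either direction called 15. Those included the TGF-beta and BMP, adipogenic, MSC marker, epithelial-mesenchymal and granulocyte lists, which camera did not call. Each list had its genes adjusted over all genes and over the list alone. The rule named Igf2, Runx2 and Nfyc, the up to 12 largest passing changes per direction, or the 5 largest moderated t per direction where fewer than 5 passed, and up to 4 members of each list with the smallest p. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

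Some planned steps could not be taken on centred values. The plan to represent a gene by its brightest probe set was replaced by the mean of its probe sets, which had been listed as another setting before the data were examined. The filter on dim genes, the trend in eBayes, the control probe sets for RNA quality and the pseudocounts were left out. Quantile normalization was also left out. The test of miR-30e seed sites needed 3' untranslated sequence that was not used here.

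The procedure was tested on simulated data for this comparison of 19935 genes with 200 changed. With equal spread, 66% of genes changed by 1 log2 unit and 90% of those changed by 2 were recovered, and 5 of 161 calls were wrong. With the arrays' observed spreads these were 58% and 91%, with 6 of 155 calls wrong. The simulated noise was independent between genes and held no structure that crosses the groups. The real arrays held both correlation and such structure, so these shares may not apply to them.

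Alternatives were a replicate block, centring of each array on its median, array weights and every probe set with 1 symbol on its own. Further ones were a 2-fold minimum, camera with estimated correlation and leaving out each array in turn. Added after seeing the data were robust eBayes, genes with 1 probe set only, weights and centring for the lists, and list-alone counts without each array, with weights and with the block.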

Results

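Total RNA was profiled on Affymetrix arrays from mesenchymal stem cells (MSCs), the adherent stromal progenitors of bone marrow that can form bone, cartilage and fat cells. The cells came from C57BL/6 mice and stably carried either a control lentivirus or a lentivirus for the microRNA miR-30e, with 3 arrays per group. The values were logarithms centred on each probe set's median over the 6 arrays, so they gave differences between arrays and no absolute level. The base of the logarithm was not given in the sources used here. Base 2 was assumed, and each fold below depends on that. After probe sets with several gene symbols or none were set aside, 19935 genes were tested. The arrays did not group by virus alone. Control replicate 2 had an SD over probe sets of 0.533, against 0.148 to 0.265 in the other 5 arrays, and it was the array farthest from the median of the 6 for 48.9% of probe sets. Control replicate 3 differed less from miR-30e replicate 1 (SD of the difference 0.242) than from control replicate 1 (0.297), and control replicate 1 differed less from miR-30e replicate 2 (0.223) than from either other control. The labels did not say whether arrays of one group came from separate cultures or animals, so p-values measured only the spread between these samples, which may be technical. The number of arrays limited the precision: an exact two-sided permutation test of 3 against 3 cannot go below p = 0.1.

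**Figure D1:**
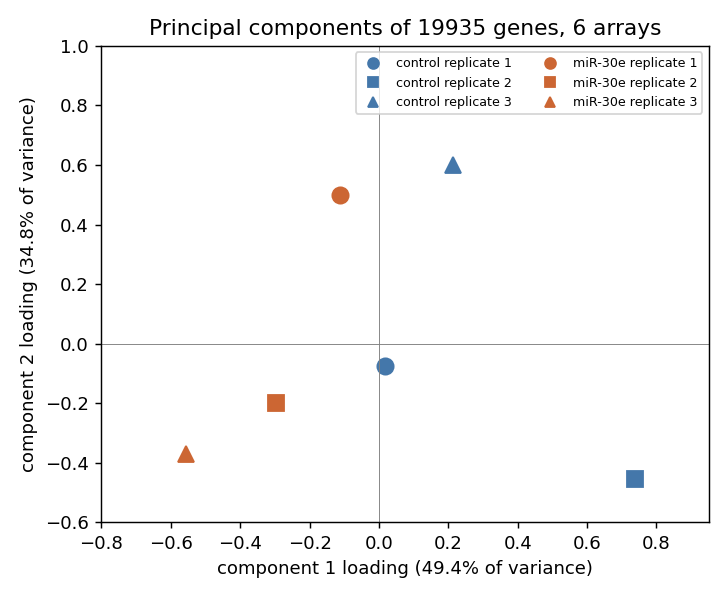
Loadings of the 6 arrays on the first and second principal components of 19935 genes (unitless axes, with the percent of variance in each label). Circles, squares and triangles are replicates 1, 2 and 3 of control (blue) and miR-30e (orange). Control replicate 2 lies farthest along component 1, which held 49.4% of the variance, at a loading of 0.74.

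The comparison asked which transcripts differed in marrow MSCs that carried the miR-30e virus. Mir30e itself rose from -3.20 ± 0.27 (SD, n = 3) in control arrays to 3.13 ± 0.19 (n = 3), a log2 difference of 6.33 (SE 0.17) or 80.5-fold, with a limma adjusted p of 0.000282. The probe set does not tell the mature microRNA from a longer transcript that carries its sequence. As the cDNA was primed with oligo(dT), the signal may come from such a transcript, and the 80.5-fold does not measure the mature microRNA. Atp1b1, a beta subunit of the sodium-potassium pump, fell from 0.91 ± 0.07 to -0.995 ± 0.16, a difference of -1.90 (SE 0.11), 3.74-fold, with adjusted p = 0.0138. Bmp4, a secreted ligand of the bone morphogenetic protein family, fell from 0.68 ± 0.08 to -0.75 ± 0.11, a difference of -1.43 (SE 0.09), 2.70-fold, with adjusted p = 0.0261. Vsnl1, a neuronal calcium sensor, fell from 0.78 ± 0.11 to -0.94 ± 0.20, a difference of -1.72 (SE 0.13), 3.31-fold, with adjusted p = 0.0371.

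These 4 genes, 1 higher and 3 lower, were all that passed at an adjusted p under 0.05 over all genes with limma. When all 28815 probe sets were tested, including those set aside, 3 probe sets passed. At an unadjusted p under 0.05 there were 1830 genes, or 9.18% of those tested, of which 1106 were higher and 724 lower with miR-30e. That count was 865 without miR-30e replicate 3, 1008 without miR-30e replicate 2 and 1644 without control replicate 2. It was 2029 without control replicate 3, 2187 without miR-30e replicate 1, 2265 without control replicate 1 and 3881 with array weights. The 3 arrays of each group did not overlap for 17.1% of genes, against 10% by chance, and these leaned the other way, with 1437 genes higher and 1973 lower. The genes next in rank did not pass. Among these, Pid1 differed by -1.10 (SE 0.09, adjusted p = 0.0567) and Penk, which encodes the opioid precursor proenkephalin, by -1.73 (SE 0.16, adjusted p = 0.111). Higher with miR-30e, and also not passing, were Trp53i11 at 0.82 (adjusted p = 0.111), the replication licensing factor Cdc6 at 0.86 (0.124), the palmitoyltransferase Zdhhc2 at 1.49 (0.143) and the junctional adhesion molecule F11r at 1.20 (0.174). Without any 1 of the 6 arrays, only Mir30e passed: the adjusted p then lay between 0.0645 and 0.185 for Atp1b1, 0.0958 and 0.206 for Bmp4, and 0.0853 and 0.230 for Vsnl1, while their differences were at most -1.82, -1.38 and -1.66. With arrays weighted by their fit, 776 genes passed, 305 higher and 471 lower, and these included the same 4. The weights lay mostly on 1 array per group. Control replicate 1 had 2.79, against 0.158 and 0.549 in the other controls. MiR-30e replicate 2 had 9.13, against 0.557 and 0.812 in the other miR-30e arrays. Results with array weights, above and below, therefore rest mainly on control replicate 1 and miR-30e replicate 2.

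**Figure D2:**
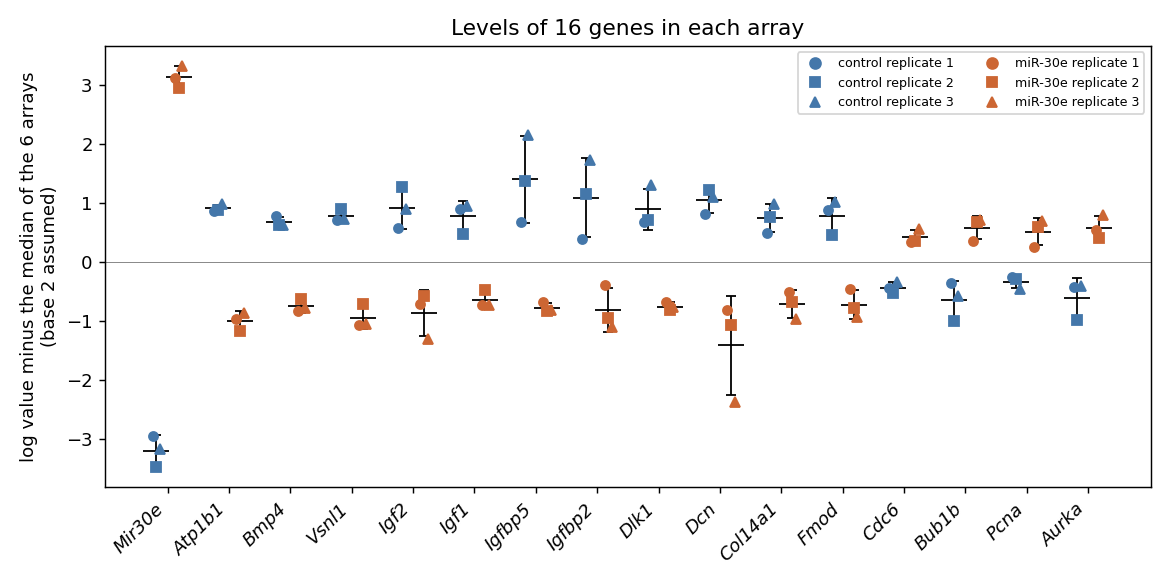
Values of 16 genes in each of the 6 arrays (vertical axis: log value minus the median of the 6 arrays, base 2 assumed). Points are arrays, bars are the mean and SD of the 3 control (blue) or 3 miR-30e (orange) arrays. Mir30e differed by 6.33 and Atp1b1, Bmp4 and Vsnl1 by -1.90, -1.43 and -1.72, and the other 12 genes did not pass over all genes.

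Within the list of insulin-like growth factors, their receptors and their binding proteins, some genes were lower with miR-30e and others did not pass. Igf1 differed by -1.42 (SE 0.15), and Igf2, a fetal growth factor expressed from the paternal allele, went from 0.91 ± 0.35 to -0.86 ± 0.39, a difference of -1.78 (SE 0.25). The binding proteins Igfbp5 and Igfbp2 differed by -2.18 (SE 0.35) and -1.90 (SE 0.36). Of the 21 measured genes of the IGF axis, 7 were lower and 0 higher when adjusted over the list alone, and 0 passed over all genes tested, where Igf2 had an adjusted p of 0.174. Besides the 4 above these were Igfbp4 (-1.22), Pappa (-0.46) and Pappa2 (-0.43), named after their values were seen, and the last pair encode proteases that cleave IGF-binding proteins. The receptors Igf1r (-0.09) and Igf2r (0.02) and the binding proteins Igfbp1 (-0.14), Igfbp3 (-0.27), Igfbp6 (-0.11) and Igfbp7 (0.09), also named after their values were seen, did not pass. The list's mean difference was -0.48, and camera called it lower (adjusted p = 7.34e-05, and adjusted p = 0.536 with an estimated correlation). The published work of this study concerns miR-30e and Igf2, so the place of Igf2 in a list is not independent evidence of its direction. The list-alone count was 5 without control replicate 2 and fell to 4 without control replicate 3 or without miR-30e replicate 2.

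Genes of DNA replication and mitosis were higher with miR-30e, by a mean of 0.99 and a median of 1.02 over 39 measured genes. All 39 differences were positive, from 0.50 to 1.56. Adjusted over the list alone, 37 were higher and 0 lower, while 0 passed over all genes tested. Cdc6 differed by 0.86 (SE 0.10), the spindle checkpoint kinase Bub1b by 1.23 (SE 0.19), the polymerase clamp Pcna by 0.85 (SE 0.14) and the mitotic kinase Aurka by 1.18 (SE 0.19). E2f1 (0.50) and Cenpe (1.08) were the 2 genes that did not pass, named after their values were seen. The list mean was -0.19, -0.86 and -0.45 in control replicates 1 to 3, and 0.19, 0.51 and 0.78 in miR-30e replicates 1 to 3, so that no control array reached a miR-30e array. Camera called the list higher (adjusted p = 3.06e-31), and the adjusted p was 0.536 with an estimated correlation. Control replicate 2, the array that stood apart, was the lowest. Without it the mean difference was 0.81 and 25 genes passed over the list alone, without miR-30e replicate 2 there were also 25, and without miR-30e replicate 3 there were 22.

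Some extracellular matrix genes were lower when adjusted over their lists alone. Of 39 matrix protein genes 33 had negative differences, and 3 passed as lower when adjusted over the list alone, none as higher. These were the fibril-associated collagen gene Col14a1 (-1.46, SE 0.17), the laminin chain gene Lama4 (-1.23, SE 0.17) and Dcn (-2.46, SE 0.41), which encodes the collagen-binding proteoglycan decorin. Col5a3 (-0.34) did not pass. Among 21 matrix protease and inhibitor genes 19 were negative, and 5 passed as lower over the list alone: the proteases Adamts12 (-0.80), Mmp23 (-1.08) and Adamts9 (-0.59) and the inhibitors Timp3 (-0.53) and Timp4 (-0.34), the last named after its value was seen. In neither list did a gene pass over all genes tested. The mean difference was -0.38 for matrix proteins (camera adjusted p = 8.45e-07) and -0.41 for proteases (8.96e-07), and for both lists the adjusted p was 0.536 with an estimated correlation. The 5 protease-list genes became 2 without control replicate 2, 10 without miR-30e replicate 1, and 0 without any 1 of the other 4 arrays, and the 3 matrix protein genes became 12 without miR-30e replicate 1. With array weights 21 matrix protein and 15 protease-list genes were lower over the list alone.

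Lists for bone, cartilage and fat formation were each tested. Of 29 measured osteogenic genes 24 were negative. Bmp4 was lower over all genes, and Bmp4 and the osteoblast cadherin Cdh11 (-0.72, SE 0.12) were the 2 lower when adjusted over the list alone, with 0 higher. Bmp6 (-0.40) and Ogn (-0.32) did not pass. The list's mean difference was -0.20 (camera adjusted p = 0.000405, and adjusted p = 0.536 with an estimated correlation). Over the list alone 1 gene passed without control replicate 1, control replicate 2 or miR-30e replicate 2, and 3 did without miR-30e replicate 1, while 9 were lower with array weights. In the chondrogenic list of 24 genes, adjusted over the list alone, 2 were higher, the cartilage collagen Col2a1 (0.67, SE 0.10) and its transcriptional regulator Sox5 (0.48, SE 0.09), and 2 were lower, the matrix proteins Fmod (-1.51, SE 0.19) and Comp (-0.42, SE 0.10). None passed over all genes. The chondrogenic mean was -0.13 (camera adjusted p = 0.0420, and adjusted p = 0.536 with an estimated correlation), and the call ended without control replicate 2 (adjusted p = 0.231) or miR-30e replicate 2 (0.0590), or with array weights (0.301). The 2 higher genes became 1 without control replicate 1, miR-30e replicate 1 or miR-30e replicate 3, and the 2 lower became 1 without any 1 array except control replicate 2 and 4 with array weights. The adipogenic list of 34 genes had a mean of 0.08 (-0.03 without control replicate 2) and was not called by camera (adjusted p = 0.466). Fry for change in either direction called it (adjusted p = 0.0136). Within it, adjusted over the list alone, the lipid droplet gene Plin4 (0.84, SE 0.16) was higher and Dlk1 (-1.65, SE 0.18), an inhibitor of fat cell differentiation, was lower, with none passing over all genes. Fabp4, a fatty acid carrier, differed by 1.26 (SE 0.29, adjusted p over the list alone 0.0508), and Retn by -0.49. Over the list alone 0 genes were higher without control replicate 1, miR-30e replicate 2 or miR-30e replicate 3, and 2 were without miR-30e replicate 1. With array weights 2 were higher and 3 lower, and the list mean was -0.01.

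Signalling lists tied to these fates held few changed genes. In the list of 49 TGF-beta and BMP genes Bmp4 and Chrdl1 (-1.66, SE 0.21), an antagonist of BMP ligands, were the 2 lower genes when adjusted over the list alone, and Bmp4 alone passed over all genes. Tgfbr2 (-0.92, SE 0.27) did not pass. Of the 49 differences 24 were positive and 25 negative. Smad7 (0.65), Smad9 (0.70) and Id2 (0.44), named after their values were seen, were among the positive ones and did not pass. The mean of this list was 0.01 and its median -0.02, which differ in sign, and camera did not call it (adjusted p = 0.820). Fry for change in either direction called the list (adjusted p = 0.000780). The mean was -0.09 without control replicate 2 and -0.02 without miR-30e replicate 1, and 2 genes were higher over the list alone without control replicate 3. With array weights the mean was -0.06, with 3 genes higher and 6 lower over the list alone. Of 43 Wnt genes 32 were negative, with a mean of -0.12, while the 1 gene that passed over the list alone was higher: Sfrp4 (1.11, SE 0.18), a secreted Wnt antagonist. Lrp6 (-0.53), Fzd3 (0.56) and Wnt16 (-0.72) did not pass, and no Wnt gene passed over all genes. Camera called the Wnt list lower (adjusted p = 0.00274, and adjusted p = 0.536 with an estimated correlation), a call that ended without control replicate 3 (mean -0.08, adjusted p = 0.0589), and the mean was -0.05 without miR-30e replicate 3. Over the list alone 2 Wnt genes were higher without control replicate 1 or miR-30e replicate 1 and 0 without any 1 of the other 4 arrays, and 3 were lower without miR-30e replicate 1. With array weights the balance turned, with 2 Wnt genes higher and 9 lower. Smooth muscle genes, 27 measured, had a mean of 0.02 (-0.09 without control replicate 2) and were not called (adjusted p = 0.874), with 0 genes passing over the list alone and over all genes. Their smallest p-values belonged to Mylk (-0.42), Pgm5 (-0.99), Csrp1 (0.39) and Tpm2 (0.71). With array weights their mean was -0.12 and 3 genes were lower over the list alone. Genes of epithelial-mesenchymal transition, 21 measured, were not called by camera (adjusted p = 0.257) but were by fry for change in either direction (adjusted p = 0.0252). In that list Cdh11 was the 1 gene lower when adjusted over the list alone, none passed over all genes, and Hmga2 (0.34), Itga5 (0.58) and Fn1 (-0.20) did not pass. That list had 1 lower gene without miR-30e replicate 1 or 3 and 0 without any 1 of the other 4 arrays.

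**Figure D3:**
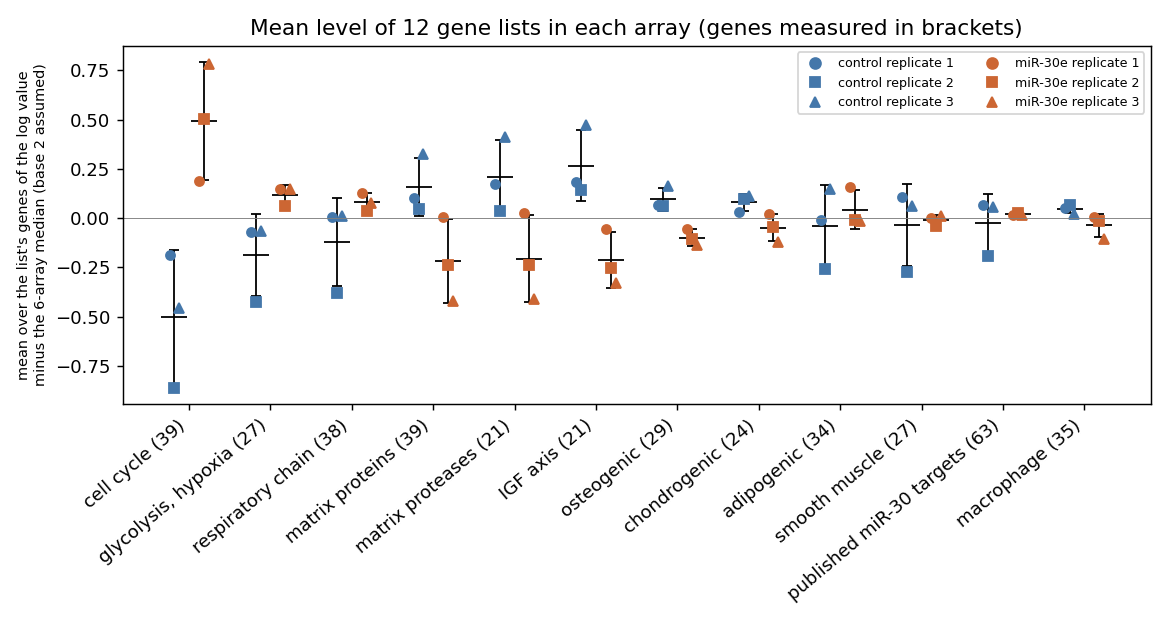
Mean of 12 gene lists in each of the 6 arrays (vertical axis: mean over the list's genes of the log value minus the median of the 6 arrays, base 2 assumed, with the number of genes measured in brackets). Points are arrays, bars are the mean and SD of the 3 control (blue) or 3 miR-30e (orange) arrays. The cell-cycle mean ranged from -0.86 to -0.19 in control arrays and from 0.19 to 0.78 with miR-30e.

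Genes of glycolysis and of the response to low oxygen had a mean difference of 0.30 over 27 measured genes. Adjusted over the list alone 10 were higher and 1 was lower, and 0 passed over all genes. The oxygen-sensing prolyl hydroxylases Egln1 (0.38, SE 0.09) and Egln3 (0.89, SE 0.21), the mitophagy receptor Bnip3 (0.78, SE 0.18) and the angiogenic factor Vegfa (0.47, SE 0.12) were among the 10. The lower gene was Ndrg1 (-0.78), named after its value was seen, and 0 genes of this list were lower over the list alone without any 1 of the 6 arrays. With array weights 9 were higher and 2 lower. Respiratory chain genes had 35 of 38 positive differences and a mean of 0.20, with 0 genes passing over the list alone or over all genes. The smallest p-values were those of Cycs (0.48) and Cox7a2 (0.32). Genes of the unfolded protein response, 29 measured, had a mean of 0.16 with 0 genes passing over the list alone or over all genes, and their smallest p-values were those of Manf (0.27) and Atf4 (0.38). Camera called the 3 lists higher, with adjusted p-values of 1.42e-06, 7.34e-05 and 0.000947, and for each the adjusted p was 0.536 with an estimated correlation. With array weights the calls of the respiratory chain list (mean 0.05, adjusted p = 0.175) and of the unfolded protein response list (mean 0.05, adjusted p = 0.0687) ended. Control replicate 2 was the lowest array in the glycolysis list at -0.42, against -0.07 and -0.06 in the other 2 controls, and in the respiratory chain list at -0.38, against 0.01 in each of the others. Without it the list means were 0.19, 0.07 and 0.05, and 1 glycolysis gene passed over the list alone. That count was 8 without control replicate 1, 1 without miR-30e replicate 1, and 0 without control replicate 3 or miR-30e replicate 2 or 3.

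Autophagy genes, 29 measured, had a mean of 0.11 (-0.01 without control replicate 2) and were not called (adjusted p = 0.145). Bnip3 (0.78) and Atg5 (0.51) had the smallest p-values there, followed by Map1lc3b (-0.24) and Gabarapl2, whose 2 probe sets differed in sign (-0.08 and 0.42). Cholesterol synthesis genes, 20 measured, had a mean of -0.03 (adjusted p = 0.674), and Pmvk (0.29) had the smallest p. Without control replicate 2 that mean was -0.19 and the list was called lower (adjusted p = 0.00102). The p53 target list, 21 measured, had a mean of -0.02 (adjusted p = 0.874), with Gadd45a at -0.81 and Sesn1 at -0.25. The cholesterol and p53 means were positive (0.05 and 0.05, 0.06 and 0.04, 0.02 and 0.01) without control replicate 1, control replicate 3 and miR-30e replicate 2. In these 3 lists 0 genes passed over the list alone and 0 over all genes. With array weights camera called cholesterol synthesis genes lower (mean -0.23, adjusted p = 7.00e-05, 1 gene higher and 7 lower over the list alone) and p53 targets lower (mean -0.18, adjusted p = 0.0281, 4 genes lower), while autophagy genes had a mean of -0.01 with 2 genes higher and 1 lower.

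The miR-30 family has many published targets, which were tested as 1 list. The 63 measured genes had a mean difference of 0.04 and a median of 0.04, with 37 positive and 26 negative, and camera did not call the list (adjusted p = 0.424). Igf2 was the 1 gene lower when adjusted over the list alone (adjusted p 0.0216), none was higher, and 0 passed over all genes. The published work of this study concerns miR-30e and Igf2, so its place in this list is not independent evidence either. The Wnt co-receptor Lrp6 (-0.53, SE 0.13), the receptor Fzd3 (0.56, SE 0.14) and the transcriptional coactivator Ppargc1a (-0.54, SE 0.14) followed and did not pass. The mean was -0.04 without control replicate 2. Over the list alone 1 gene was lower without control replicate 1 and 0 without any 1 of the other 5 arrays. With array weights the mean was -0.03, with 2 genes higher and 4 lower over the list alone. Nfyc, a subunit of the transcription factor NF-Y and the host gene of Mir30e, differed by 0.07 (SE 0.11, adjusted p = 0.816). Runx2, a further gene named in advance, was not analysed here. Genes of microRNA processing and silencing, 24 measured, had a mean of 0.14 with 0 passing over the list alone or over all genes, and the deadenylase subunit Cnot6l (0.36) had the smallest p. Camera called this list higher (adjusted p = 0.0165, and adjusted p = 0.536 with an estimated correlation), a call that ended without control replicate 2 (mean 0.07, adjusted p = 0.117), control replicate 3 (0.0943) or miR-30e replicate 3 (0.0967), or with array weights (0.172), and the mean was 0.22 without control replicate 1.

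Surface and niche markers of MSCs, 24 measured, had 9 positive and 15 negative differences with a mean of -0.11. Camera did not call them (adjusted p = 0.185), while fry for change in either direction did (adjusted p = 0.0252). Without 1 array the mean lay between -0.16 (without control replicate 2) and -0.07 (without control replicate 1). The adhesion receptor Vcam1 differed by -1.27 (SE 0.27), Thy1 by -0.87 (SE 0.24), Cd200 by -0.53 and Angpt1 by -0.58, while Nt5e (0.62) and Cspg4 (0.81), named after their values were seen, came next, and 0 genes passed over the list alone or over all genes. Over the list alone 1 gene was lower without miR-30e replicate 1 or 3, and with array weights 1 was higher and 5 were lower. Interferon-response genes, 34 measured, had a mean of -0.11 (camera adjusted p = 0.0322, and adjusted p = 0.564 with an estimated correlation), with Xaf1 at -0.49 and Ifitm3 at -0.34. That call ended without control replicate 1 (mean -0.05, adjusted p = 0.290), control replicate 3 (0.0758) or miR-30e replicate 3 (mean -0.06, adjusted p = 0.0967), and the mean was -0.19 without control replicate 2. Inflammatory mediators, 35 measured, were not called (adjusted p = 0.257), except without miR-30e replicate 1 (0.0490). Besides Vcam1, Ptgs2 (1.27, SE 0.36) and Il33 (-0.34) had the smallest p-values. In both lists 0 genes passed over the list alone and 0 over all genes, while 1 inflammatory gene was lower over its list without miR-30e replicate 3. With array weights 4 interferon-response and 3 inflammatory genes were lower over their lists.

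Markers of other cells that marrow cultures can hold had small mean differences. Of 35 macrophage genes 29 were negative, with a mean of -0.08 and with Lyz2 at -0.64 and Lyz1 at -0.42, and 0 passed over the list alone or over all genes. Of 20 lymphoid genes 19 were negative, with a mean of -0.11 and Cd3e at -0.28, and again 0 passed. In the endothelial list of 23 genes, mean -0.11, the 1 gene lower when adjusted over the list alone was the VEGF receptor Flt1 (-0.43, SE 0.08), and in the osteoclast list of 13, mean -0.17, it was the proton pump subunit Atp6v0d2 (-0.96, SE 0.19). The osteoclast protease Ctsk (-0.89) did not pass, and no gene of either list passed over all genes. Camera called these 4 lists lower, at adjusted p = 0.00966 for macrophage and endothelial genes, 0.0165 for lymphoid and 0.0481 for osteoclast genes. The adjusted p was 0.536 with an estimated correlation for macrophage, endothelial and osteoclast genes and 0.603 for lymphoid genes. Without control replicate 2 none of the 4 was called (0.112, 0.134, 0.423 and 0.129 in the same order), nor were lymphoid genes without miR-30e replicate 3 (0.0710), nor osteoclast genes without control replicate 3 (0.104) or miR-30e replicate 3 (0.1004). The lymphoid mean was -0.04 without control replicate 2. In that array the lymphoid list mean was 0.21, against -0.01 and 0.02 in control replicates 1 and 3, and -0.01, 0.02 and -0.11 in miR-30e replicates 1 to 3. Much of the lymphoid difference was therefore a high value in 1 control array. Without miR-30e replicate 3 the means were -0.05 for macrophage, -0.07 for lymphoid, -0.08 for endothelial and -0.10 for osteoclast genes. Flt1 did not pass over its list without any 1 of the 6 arrays, and the osteoclast list had 0 such genes without control replicate 3, miR-30e replicate 2 or miR-30e replicate 3 and 2 without miR-30e replicate 1. With array weights the calls of endothelial (0.380), lymphoid (0.996) and osteoclast genes (0.300) ended, and 3 endothelial, 2 osteoclast, 1 macrophage and 2 erythroid genes were lower over their lists. Granulocyte genes (21 measured, mean -0.05, adjusted p = 0.145) and erythroid genes (9 measured, mean -0.04, adjusted p = 0.0714) were not called by camera. In both, 0 genes passed over the list alone or over all genes, except that 1 erythroid gene was higher over its list without miR-30e replicate 1. Fry for change in either direction called the granulocyte list (adjusted p = 0.0252). Without 1 array the means lay between -0.085 and -0.024 for granulocyte genes and between -0.062 and -0.003 for erythroid genes. In these lists the stem cell factor receptor Kit (0.46) and the erythroid gene Rhag (-0.33) had the smallest p-values. The sex-linked genes did not separate the groups: Uty differed by 0.35, Eif2s3y by 0.26, Kdm5d by 0.12 and Xist by -0.03, and their list was not called (adjusted p = 0.332).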

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

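The alternatives chosen after the data were seen were robust eBayes, genes with 1 probe set only, array weights and median centring for the lists, and list-alone counts without each array, with weights and with the block. Mir30e passed with every alternative run for it, at differences of 5.99 to 6.46. The 4 genes passed with robust eBayes, with 1-probe-set genes only and with centring (which added Pid1, 5 in all). There were also 4 calls with each of the 21780 probe sets with 1 symbol tested on its own, and with a 2-fold minimum. With all 28815 probe sets tested, 3 passed, and 0 of these had been set aside. With array weights, estimated without reaching convergence, 776 genes passed, and the cause was not tested. The weights ran from 0.158 for control replicate 2 to 9.13 for miR-30e replicate 2. Control replicate 1, at 2.79, had most of the weight of its group, as miR-30e replicate 2 had of its own. Leaving out each array in turn left from 1 to 1 gene, with fewer samples in each fit. With the replicate block 1 gene passed (Mir30e). The deviations of same-numbered arrays correlated at -0.557, 0.379 and -0.455, so the numbers were not taken to pair samples. Of the 16 lists called, 0 were called with an estimated correlation, which was as high as 0.648 for cell-cycle genes, 15 with the block (all but the osteoclast list), 11 with weights (9 of the 16, with cholesterol and p53 lists added), and 11 to 17 without 1 array, and 8 were called in all 6 of those fits. With the block the list-alone counts were 26 for cell-cycle, 6 for IGF, 0 for glycolysis and 0 for protease genes, and with weights they were 38 higher, 9 lower, 9 higher with 2 lower, and 15 lower in the same order.

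Signs turned for genes that did not pass and for lists not called with all arrays, except for the lymphoid list. The cholesterol synthesis mean turned positive without control replicate 1 (0.0474), control replicate 3 (0.0636) or miR-30e replicate 2 (0.0203), and camera did not call the list in those fits. Without control replicate 2 that mean kept its sign at -0.189, and camera called the list lower (adjusted p = 0.00102). With weights the means were -0.0309 for miR-30 targets, -0.00772 for adipogenic, -0.117 for smooth muscle, -0.0603 for TGF-beta and BMP, -0.00817 for autophagy and 0.00350 for lymphoid genes, the 1 of these called without weights, and Nfyc was at -0.107. Without 1 array the means ranged from -0.0422 to 0.0886 for miR-30 targets, -0.0282 to 0.176 for adipogenic, -0.0944 to 0.0945 for smooth muscle, -0.0885 to 0.0844 for TGF-beta and BMP, -0.0110 to 0.172 for autophagy, -0.189 to 0.0636 for cholesterol synthesis, -0.154 to 0.0550 for p53 target and -0.0976 to 0.000814 for epithelial-mesenchymal genes. The ranges were -0.00256 to 0.136 for Nfyc, -0.0531 to 0.00399 for Xist and -0.00725 to 0.324 for Kdm5d. The cause was not tested. Not run, for want of levels or sequence, were quantile normalization, the dim-gene filter, the eBayes trend, pseudocounts and the seed-site test with its alternatives. Signal over background is unknown for these values.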

Other observations

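The tests of a wrong label, of sex, of whether 1 array decides the cell-cycle difference, of other splits of the arrays, and of the order of the arrays in the imprinted and cell-cycle lists were chosen after the result was seen, as were all gene lists named in this part except the cell-cycle list and the lists of lineage, matrix, respiratory chain and MSC marker genes.

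Some further gene groups were picked after their genes had been seen to differ, so their values describe these arrays and do not test the groups. In each group 0 genes passed over all genes, except for Mir30e in its family. Small leucine-rich proteoglycans, which bind collagen fibrils, had 13 of 14 negative differences and a mean of -0.57, and 7 of the 14 also belong to lists fixed in advance. Adjusted over the list alone, Fmod (-1.51), Podn (-1.69) and Dcn (-2.46) were lower and 0 were higher, and of these Fmod and Dcn were already counted among chondrogenic and matrix protein genes. Histone genes, 26 measured, had a mean of 0.64 with 25 positive, among them H2bc8 (0.78) and H1f3 (0.64). All 54 small nucleolar RNA genes were positive, with a mean of 0.61, and Snora74a (0.93) and Snora21 (1.41) had the smallest p-values. The mean of that list in control replicate 2 was -0.94, against 0.03 and -0.31 in the other 2 controls. In miR-30e replicates 1 to 3 it was 0.38, 0.0013 and 0.25, so the groups overlapped, control replicate 1 lying above miR-30e replicate 2. Ribosomal protein genes, 57 measured, had a mean of 0.08, with 37 positive and 20 negative.

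Of the other miR-30 family members, Mir30a was at 0.53 (SE 0.09), which passed over the 6 family genes alone and not over all genes (limma adjusted p = 0.196). The rest did not pass, with Mir30b at 0.04, Mir30c-1 at -0.05, Mir30c-2 at 0.03 and Mir30d at -0.14. The 5 Serpinb9 family genes had a mean of 0.99, with miR-30e replicate 3 at 1.88 and the other miR-30e arrays at -0.08 and 0.56. Immediate early genes, 21 measured, had a mean of 0.12 with 15 positive and 6 negative, and were at 0.50 in miR-30e replicate 1, against -0.16 and -0.20 in the other miR-30e arrays.

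Other splits of the 6 arrays into 3 and 3 were tested for the 4 genes called. Of the 10 splits, 2 gave as many genes, the real one included, and the other, control replicate 1 and miR-30e replicates 2 and 3 against the remaining arrays, gave 415 genes, which held none of the 4. At an unadjusted p under 0.05 the real split gave 1830 genes, and 2 of the others gave 1886 and 2992. With 10 splits there are too few to give a share under 0.05. A split that calls so many more genes than the real one points to a structure of the samples other than the virus.

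Control replicate 2 stood apart from the other 5 arrays. A miR-30e culture carrying a control label was argued against by Mir30e, which was at -3.48 there, 6.43 below the lowest miR-30e array, and cells of the other sex by Uty, Eif2s3y and Kdm5d, whose mean was -0.18 relative to the other arrays. Array or RNA quality remained a candidate explanation: lymphoid, granulocyte and erythroid genes, 50 in all, lay 2.87 times as far from the other arrays as was usual for the other 5, against 2.30 times for all genes and 1.51 times for 101 genes of matrix, respiratory chain and MSC markers. The lineage ratio was 1.89 in miR-30e replicate 3, so it was not raised in control replicate 2 alone. These ratios measure distance without direction. In control replicate 2 the list means were 0.21 for lymphoid, 0.09 for granulocyte and 0.09 for erythroid genes, each the highest of the 6 arrays. The test took these lineages to be absent from the cultures, which centred values cannot show. It therefore could not tell array or RNA quality from cells of these lineages in that sample. No biological explanation other than sex was tested.

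Cell-cycle genes had a higher list mean in each miR-30e array than in each control array, and whether more cells were dividing was not tested. That 1 array decides it was argued against, since the mean difference was still 0.81 or more without any 1 array. Against the array structure that crosses the groups, miR-30e replicate 1 exceeded control replicate 3, which it resembles, by 0.642, more than the spread of 0.451 of a difference between 2 arrays of a group. That structure still stayed open. The lowest miR-30e array exceeded the highest control by 0.376, more than the standard error over genes of 0.0673 set in advance as the bound, but that bound treated genes as independent although their estimated correlation was 0.648, and 0.376 lies within the spread of 0.451, so the structure and the virus cannot be told apart with 3 arrays per group.

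Igf2, Dlk1, Mest and Dio3, which are imprinted, prompted the hypothesis that imprinted growth-related genes are lower with miR-30e. Over 39 other imprinted genes 30 were negative, with a median of -0.09, and Peg10 (-0.96) was the 1 gene lower when adjusted over the list alone, with 0 over all genes. Peg10 had a smaller unadjusted limma p (0.000202) than Mest (0.000330) and Igf2 (0.000343), so this list may not be independent of the search that prompted the idea. Lymphoid (19 of 20 negative, median -0.09) and endothelial genes (18 of 23, median -0.12) leaned lower as much, while lists such as the cell-cycle genes leaned higher. Camera gave p = 0.00413 at the preset correlation and p = 0.149 with an estimated one, so the test left the hypothesis open. That these genes could follow the cell-cycle change was also left open: the 2 list means ordered the arrays in opposite ways in 1 of the 2 groups, the miR-30e arrays, while in the controls they ordered the arrays alike, which goes against it. Order took the place of the correlation first planned, which 3 arrays per group cannot support.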
